A study of Mus musculus with 8 samples.

How the data were processed

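RNA was extracted with Trizol from 8 mouse malignant peripheral nerve sheath tumors, and Illumina TruSeq poly-A libraries with dual indexes were made from it, per the labels' protocols. The submitters' processing notes name Trim Galore for read trimming, STAR 2.6 for alignment, Partek 7.0 and the mouse build mm10; the order of steps, the annotation, the counting method, strand use and any gene filter are not given in the sources used here. The authors deposited 1 table of quantile-normalized log2 gene counts for 20943 gene symbols and 8 tumors. Quantile normalization gives every tumor nearly the same distribution of values, so the deposited log2 values hold no library totals, and all tumors had a median near 8.46 and a highest value of 18.764. Of 2567 values between 0.05 and 0.5, 2283 lie on multiples of 1/9, 2227 on multiples of 1/6 and of 1/12, and 0 on multiples of 1/8 within rounding in R. How many libraries were normalized together is not given in the sources and these values do not settle it; 8 are in the table. Sequencing depth is therefore unknown and no counting interval is given. The offset added before the log is not stated; a fold change is 2 raised to a difference of deposited log2 values and understates the change of low genes. A value of 0 is reported only as listed at 0, with no fold against a group entirely at 0. None of the 15 housekeeping genes was at 0 in any tumor.

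Tumors were grouped by the PRC2 status in their titles, 5 wildtype and 3 loss, and each table column was matched to a tumor by its description. The titles call the tumors biological replicates, but codes show 3 wildtype and 2 PRC2 loss animal numbers, and the labels do not say more about the mice.

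Genes constant over all tumors (136) were left out and 20807 were tested. The main test was a linear model in limma 3.58.1 (R 4.3.3) with empirical Bayes variances trended on the mean, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. No pseudocount was added. Of these genes 9578 had an unadjusted p below 0.05. Gene lists for pathways and for cell types that a dissected tumor may hold were fixed before the data were examined, and 34 with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. A further list of mitochondrially encoded genes had none of its members in the table. The genes named in the text follow a rule fixed at the same time. It took the engineered alleles and PRC2 subunits, and the 12 largest rises and 12 largest falls past the threshold whose groups did not overlap and whose higher group mean reached the median of all gene means, 8.43. It then took up to 4 members of each list, by smallest p among those past the threshold and then by highest mean, and passed over predicted genes in the top 12. This left 165 genes after some that are not reported here singly, though they stay in every fit and list. List members outside the rule, such as the few that moved against the rest of their list, were named after their values were seen, and the additional families and genes in the closing section were all chosen that way.

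Gene positions came from GENCODE release M21, whose assembly is mm10, by symbol; 19873 of the tested symbols matched 1 gene. The procedure was tested on simulated data for this comparison with 20807 genes. Of 50 genes each shifted by 1, 2, 3 and 4 on the log2 scale, 46%, 78%, 96% and 96% were recovered. There were 7 calls among 20607 unchanged genes. The shifted genes all had a mean at or above the median of all gene means. They were far fewer than the 7424 genes that differed between the real groups, and the adjusted threshold depends on that share. The simulated noise was normal and independent between genes and tumors, with no floor at 0. These rates therefore do not cover low genes, correlated genes, tumors that share a mouse or a comparison in which as many genes differ as here. Alternatives were leaving out low genes, pseudocounts of 1 and 16 on the linear scale, other variance priors, array weights, centring on housekeeping genes or on the genes above the median, animal number as a block or averaged, the replicate number as a block, covariates for skeletal muscle, macrophage content and sex, and leaving out each tumor in turn. Fits without the male tumors and without wildtype tumors 1 and 2 were added after seeing the data, and so was camera at an estimated correlation in every alternative but the random block.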

Results

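RNA from 8 mouse malignant peripheral nerve sheath tumors (MPNST), sarcomas of the Schwann cell lineage, was profiled by poly-A RNA sequencing. In all 8 tumors the floxed tumor suppressor genes Nf1, a negative regulator of Ras, and Cdkn2a, which encodes p16INK4a and p19ARF, were the targets of Plp-CreERT, a tamoxifen-inducible recombinase active in Schwann lineage cells. Pups received 0.4 mg tamoxifen between day 0 and day 3 after birth. The 3 PRC2 loss tumors also carried floxed Eed, which encodes a core subunit of Polycomb repressive complex 2 (PRC2), the complex that methylates histone H3 at lysine 27; the 5 PRC2 wildtype tumors did not. The series asks how loss of PRC2, named in its title as a tumor suppressor in MPNST, alters these tumors. The deposited values are quantile-normalized log2 gene counts for 20943 genes, and sequencing depth is unknown. Between 2686 and 3372 genes were listed at 0 in each wildtype tumor, and between 1822 and 2113 in each PRC2 loss tumor. PRC2 loss tumor 1 came from a right paraspinal nerve, and tumors 2 and 3 from the left and right sciatic nerves under 1 animal code. The sites of the wildtype tumors are not given, and their codes pair tumor 1 with 2 and tumor 3 with 4, so the 8 tumors carry only 3 wildtype and 2 PRC2 loss animal numbers. If a shared number marks a shared mouse, the p-values treat tumors of 1 mouse as independent and are too small.

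Eed transcripts were lower in every PRC2 loss tumor than in every wildtype tumor. The Eed value was 10.25 ± 0.08 (SD, n = 5) in wildtype and 8.89 ± 0.11 (SD, n = 3) in PRC2 loss, a log2 difference of -1.36 (SE 0.115) or 0.389-fold, with limma adjusted p = 0.00021. A two-sided exact permutation test over the 56 splits of the tumors gave p = 0.0179, the smallest value this design allows. Of the other core subunits, Ezh2, the main methyltransferase, fell by 1.00 on the log2 scale (limma adjusted p = 0.00832) and Suz12 by 0.78 (limma adjusted p = 0.0196), while the core subunits Rbbp4 and Rbbp7 did not pass the test (limma adjusted p = 0.160 and 0.762). The accessory subunit Phf19 fell by 2.68 and Aebp2 by 0.50, while Ezh1, the alternative methyltransferase, rose by 1.05 and Epop, a partner of the complex, by 1.27. Jarid2, Mtf2 and Phf1 did not pass the test. With 2 of 12 members higher and 5 lower, both over all genes and adjusted over the list alone, the PRC2 subunit list did not pass limma's camera test (adjusted p = 0.554). Nf1, targeted in both groups, stood at 11.11 ± 0.26 (SD, n = 5) and 11.29 ± 0.17 (SD, n = 3), a difference within the spread of the tumors. Cdkn2a was listed between 7.43 and 8.17 in wildtype and at 10.58, 11.004 and 5.67 in PRC2 loss tumors 1 to 3; it did not pass the test with all 8 tumors (limma adjusted p = 0.351) but did without PRC2 loss tumor 3 (limma adjusted p = 0.00104). These are whole-gene values, so transcripts that lack a deleted exon still count toward them. In mm10 coordinates Eed lies on chromosome 7 from 89954654 to 89980983, Nf1 on chromosome 11 from 79339693 to 79581612 and Cdkn2a on chromosome 4 from 89274471 to 89294653. The calls for Ezh2, Suz12 and Aebp2 were lost when tumors were centred on housekeeping genes (limma adjusted p = 0.0554, 0.127 and 0.464) and when tumors sharing an animal number were averaged (0.0722, 0.0772 and 0.108); averaging also ended the call for Epop (limma adjusted p = 0.0567). Suz12 and Aebp2 also missed the threshold without PRC2 loss tumor 2 (limma adjusted p = 0.0643 and 0.0713) or tumor 3 (0.0649 and 0.0791).

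**Figure D1:**
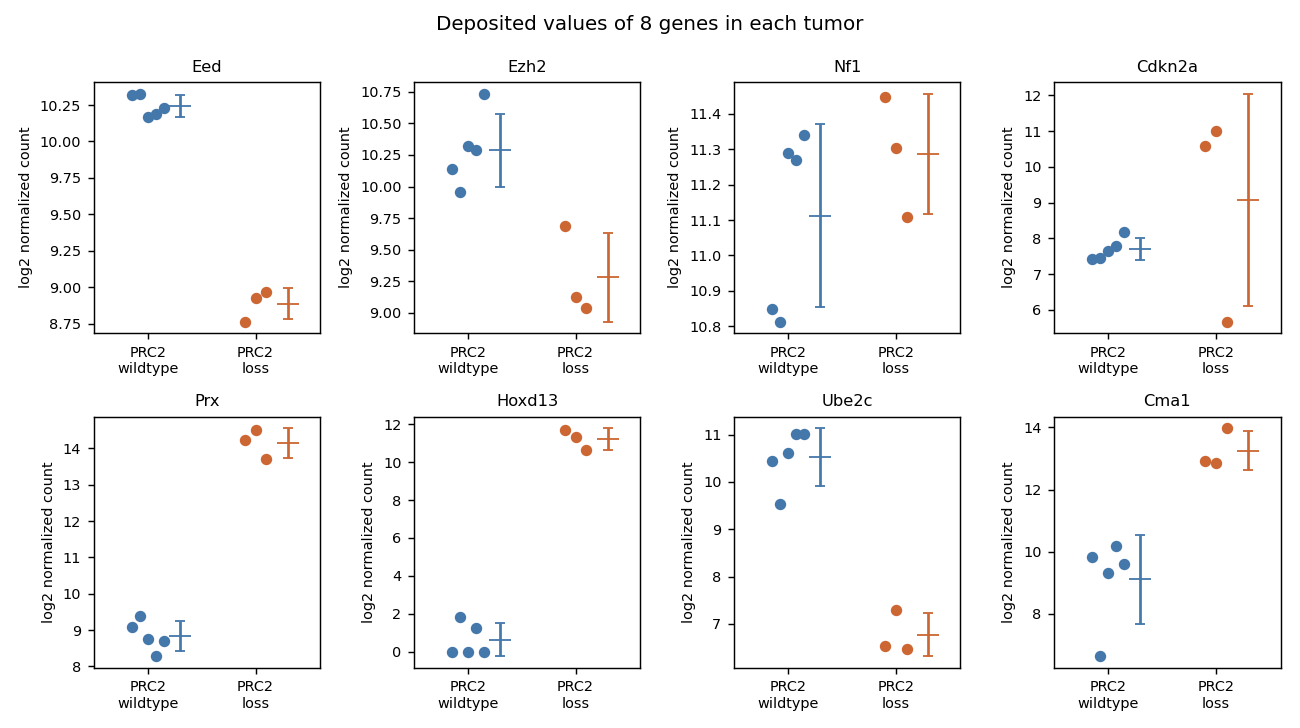
Quantile-normalized log2 values of 8 genes, with 1 point per tumor for the 5 PRC2 wildtype (blue) and 3 PRC2 loss tumors (orange) and, beside the points, the mean and SD. The vertical axes differ between panels and do not start at 0; Eed lies between 10.17 and 10.33 in wildtype and between 8.76 and 8.96 in PRC2 loss, while Cdkn2a spreads from 5.67 to 11.004 among PRC2 loss tumors.

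Of 20807 genes tested, 7424 (35.7%) differed between PRC2 loss and wildtype tumors, 3337 of them higher and 4087 lower in PRC2 loss. At least 2-fold differences were found for 2533 higher and 2522 lower genes. The largest rises included Vit, an extracellular matrix gene (12.80 ± 0.04, SD, n = 3, against 2.15 ± 1.28, SD, n = 5). Tnmd, a tendon and ligament marker, the adhesion gene Tenm2, the forkhead factor Foxd1, Cnpy1 and the protease inhibitor gene A2m were among the 12 largest rises too. Hoxd13, a distal limb and genital patterning factor, averaged 0.62 ± 0.87 in wildtype and 11.22 ± 0.56 in PRC2 loss, and the homeobox genes Nkx2-3 and Barx1, together with Etnppl and Nxf3, were listed at 0 in all 5 wildtype tumors and averaged 9.18, 9.13, 9.11 and 8.86 in PRC2 loss. The largest falls included Hmga2, a chromatin architectural factor (80.1-fold lower), Crabp1, a retinoic acid binding protein (64.3-fold), Fosl1, an AP-1 subunit (135-fold), Grem1, a secreted BMP antagonist (79.8-fold), Tnn, a tenascin (364-fold), and Il12b, a cytokine subunit (78.6-fold). Trim12a on chromosome 7 averaged 9.93 ± 0.64 in wildtype and 1.17 ± 0.67 in PRC2 loss, and Klra18, an NK cell receptor gene, 9.97 ± 1.92 and 1.69 ± 1.46; both belong to families of close copies that can share reads, so these values are uncertain. The remaining large falls were Brinp3, Krt18, Dmp1 and Nefl. Groups did not overlap for 7978 tested genes (38.3%), against 3.57% by chance. The split of higher against lower genes depended on scaling: centring each tumor on 15 housekeeping genes gave 5332 higher and 2267 lower and moved the median log2 difference of all genes from -0.124 to 0.218. Averaging tumors that share an animal number left 4226 genes, 2113 in each direction.

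Many genes of embryonic patterning rose in PRC2 loss. Among 39 Hox cluster genes, which set position along the body axis, 19 rose and 4 fell (20 and 4 adjusted over the list alone), with a median log2 difference of 2.64. Posterior members led: Hoxb13, Hoxc13 and Hoxa13 averaged 8.94 ± 0.24, 8.04 ± 0.86 and 5.86 ± 0.49 (SD, n = 3) in PRC2 loss and below 0.35 in wildtype, where 4 of 5 tumors were at 0 for each. The 4 that fell, Hoxb2, Hoxb4, Hoxd1 and Hoxd3, lie toward the anterior end of their clusters and are named here after their values were seen. Of 137 other developmental transcription factors, 78 rose and 9 fell (84 and 10 adjusted over the list alone), with a median of 2.49. Tal1, a hematopoietic and endothelial factor, was 13.5-fold higher (11.32 ± 0.02 against 7.57 ± 0.08), and the homeobox gene Hmx1, at 0 in all wildtype tumors, averaged 6.90. Both lists passed limma's camera (adjusted p = 2.79e-05 and 8.68e-15) and, narrowly, with an estimated correlation (adjusted p = 0.035 for each). The latter calls were lost in 19 of 25 alternatives for Hox genes and 16 of 25 for the other factors, among them animal numbers averaged (adjusted p = 0.238 and 0.0513 with an estimated correlation), the PNCE7 tumors averaged (0.0605 for each), housekeeping centring (0.274 for each) and sex as a covariate (0.0706 for each). Of 35 imprinted genes 13 rose and 1, Igf2r, fell (15 and 1 adjusted over the list alone; median 1.32). The growth factor gene Igf2 was 90.1-fold higher, the CDK inhibitor gene Cdkn1c 30.2-fold, Nap1l5 23.5-fold and Zdbf2 207-fold. The imprinted list had limma camera adjusted p = 8.7e-05, and adjusted p = 0.127 with an estimated correlation. With genes below the median of all gene means left out, 6 Hox genes remained and their median was -0.42 (limma camera adjusted p = 0.847). That filter takes the mean over all 8 tumors, so it removes genes near 0 in the 5 wildtype tumors. Hoxd13, Hoxb13, Hoxc13 and Hoxa13 were among those removed, so this median says nothing about them.

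Myelin genes rose almost uniformly in PRC2 loss. Of 23 myelin genes 21 rose and none fell, over all genes and adjusted over the list alone, with a median log2 difference of 5.31. The list mean was 12.05 ± 0.29 (SD, n = 3) in PRC2 loss and 6.90 ± 0.67 (SD, n = 5) in wildtype. Prx, a scaffold protein of myelinating Schwann cells, was 39.7-fold higher, its partner Drp2 56.9-fold, Pmp22, a compact myelin protein, 11.2-fold, and the tight junction gene Cldn19 359-fold. Egr2, the master transcription factor of Schwann cell myelination, was 4.01-fold higher. Of 36 Schwann cell and neural crest genes 15 rose and 6 fell (17 and 6 adjusted over the list alone; median 2.20). S100b, a Schwann cell marker, was 67.3-fold higher, whereas Gap43, a growth-associated protein of immature and repair Schwann cells, was 28.2-fold lower and Tfap2a, a neural crest transcription factor, 13.9-fold lower. Limma's camera gave adjusted p = 6.67e-16 for the myelin and 0.00557 for the Schwann cell list, and adjusted p = 0.127 and 0.518 with an estimated correlation. Each PRC2 loss tumor and no wildtype tumor was labelled with a nerve of origin. The descriptions of all wildtype samples end in the word Tumor, while those of the PRC2 loss samples name only the nerve. The titles call every sample an MPNST, so the labels do not settle how much nerve the PRC2 loss samples held. Centring on housekeeping genes ended the call of the Schwann cell list (limma camera adjusted p = 0.0835), and averaging by animal number left 7 of its members higher.

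Cell cycle genes fell in PRC2 loss tumors almost without exception. Of 46 such genes 45 fell and none rose (46 lower adjusted over the list alone), with a median log2 difference of -3.00 and list means of 10.48 ± 0.49 (SD, n = 5) in wildtype and 7.66 ± 0.48 (SD, n = 3) in PRC2 loss. Ube2c, a mitotic ubiquitin-conjugating enzyme, was 13.4-fold lower, Uhrf1, needed to maintain DNA methylation, 11.8-fold, the replication factor gene Cdc45 8.54-fold and Pcna, the replication clamp, 2.16-fold. The list passed limma's camera with adjusted p = 6.84e-21, and had adjusted p = 0.456 with an estimated correlation. Of 23 p53 target genes 9 rose and 5 fell, over all genes and adjusted over the list alone (median 0.38; limma camera adjusted p = 0.159). The CDK inhibitor gene Cdkn1a was 3.43-fold, Trp53inp1 3.47-fold and Plk2 2.85-fold higher, and Gtse1, a mitotic gene, was 11.9-fold lower; Ccng1, Bax, Bbc3 and Sesn2 fell too and are named here after their values were seen. Of 23 Ras/MAPK output genes 3 rose and 9 fell, again also adjusted over the list alone, with a median of -0.56 (limma camera adjusted p = 0.0542). Myc was 4.54-fold and the potassium channel gene Kcnn4 4.45-fold lower, Fosl1 and Hmga2 were lower as above, and the 3 that rose, named after their values were seen, were Spry4, Etv4 and Epha4. That list passed in 11 of 26 alternatives (limma camera adjusted p from 0.0128 to 0.0469), among them housekeeping centring (0.0291) and animal numbers averaged (0.0345). With an estimated correlation the adjusted p was 0.691 with all 8 tumors, 0.633 with housekeeping centring and 0.701 with animal numbers averaged. The p53 list passed in 2 alternatives, with genes below the median mean left out (limma camera adjusted p = 0.0359) and without PRC2 loss tumor 3 (0.0488), and had adjusted p = 0.709 and 0.438 with an estimated correlation in those fits.

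Markers of T and NK cells, macrophages and dendritic cells fell, and so did chemokine genes. Of 28 T and NK cell markers 22 fell and none rose (26 lower adjusted over the list alone; median -2.30). Ncr1, an NK receptor, was 13.9-fold, Ctla4, a T cell checkpoint receptor, 10.6-fold, and the cytotoxic effector genes Prf1 and Gzmb 9.47-fold and 7.61-fold lower. Of 25 macrophage and monocyte markers 14 fell and 1, Cd163, rose (17 and 2 adjusted over the list alone; median -1.21), with Ms4a7 6.25-fold, Adgre1 3.75-fold, Itgam 3.32-fold and Cd68 2.59-fold lower. Of 12 dendritic cell markers 8 fell and 2, Zbtb46 and Siglech, rose (9 and 2 adjusted over the list alone; median -2.15); Ccr7, a lymph node homing receptor, was 24.9-fold and Xcr1 12.3-fold lower. Of 32 chemokine genes 14 fell and none rose (17 lower and 1 higher adjusted over the list alone; median -1.49), with Ccl22 52.5-fold, Ccl2 12.7-fold and Ccl8 6.87-fold lower. Limma's camera adjusted p was 1.52e-06 for T and NK cells, 0.00109 for macrophages, 0.0242 for dendritic cells and 0.000683 for chemokines. With an estimated correlation the adjusted p was 0.518, 0.631, 0.642 and 0.518 in the same order. Averaging tumors by animal number left 7 T and NK cell, 5 macrophage and 6 dendritic cell markers lower, and the dendritic cell list no longer passed in 5 of 26 alternatives (limma camera adjusted p from 0.0569 to 0.725), among them without wildtype tumor 2 (0.0569), with array weights (0.0931) and with genes below the median mean left out (0.133). That last setting also ended the chemokine call (limma camera adjusted p = 0.0775). A macrophage covariate ended the calls for T and NK cells (0 of 28 lower in limma, median -0.43, limma camera adjusted p = 0.255), dendritic cells (0.725) and chemokines (0.331), but the macrophage means of the groups do not overlap (correlation with PRC2 status -0.787), so this covariate takes up much of the group difference and does not show what the fall depends on.

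Antigen presentation genes were lower in part. Of 12 MHC class II genes 6 fell and none rose, over all genes and adjusted over the list alone (median -1.57), among them the cathepsin gene Ctss at 3.70-fold and the thiol reductase gene Ifi30 at 3.57-fold lower. Of 21 MHC class I pathway genes 6 fell and none rose (3 lower adjusted over the list alone; median -0.70): the peptide trimming enzyme gene Erap1 was 1.95-fold, the proteasome activator gene Psme2 2.39-fold and Tapbpl 2.16-fold lower. The lists had limma camera adjusted p = 0.0161 and 0.0486, and adjusted p = 0.691 and 0.738 with an estimated correlation. Of 43 interferon response genes 2 fell, Irf1 at 2.54-fold lower and Ifi44l, listed at 0 in all 3 PRC2 loss tumors. Ifi44l was near the floor in wildtype too, at 1.35 ± 0.80 (SD, n = 5) with 1 tumor at 0. Adjusted over the list alone 1 gene was lower, and the list median was -0.76 (limma camera adjusted p = 0.0639). Oasl2 did not pass the test, at 12.39 ± 1.14 (SD, n = 5) in wildtype and 11.91 ± 1.22 (SD, n = 3) in PRC2 loss. Of 12 B and plasma cell markers 4 fell, also adjusted over the list alone, namely Mzb1 at 9.53-fold, Cd22 at 5.25-fold, Fcrla at 4.89-fold and Jchain at 2.72-fold lower (limma camera adjusted p = 0.0647). The class I call was lost in 15 of 26 alternatives (limma camera adjusted p from 0.0504 to 0.648), among them animal numbers averaged (0.0779), array weights (0.131), the skeletal muscle covariate (0.132) and leaving out wildtype tumor 1, 2 or 4 or PRC2 loss tumor 1. The class II call was lost in 5 of 26 (limma camera adjusted p from 0.0638 to 0.226), among them array weights (0.0638), genes below the median mean left out (0.13) and PRC2 loss tumor 1 left out (0.0796). The interferon list passed downward in 10 of 26 alternatives and the B cell list in 9 of 25, both with housekeeping centring (limma camera adjusted p = 0.00523 and 0.0142). With an estimated correlation their adjusted p was 0.824 and 0.729 with all 8 tumors and 0.734 and 0.633 with that centring. Under a macrophage covariate the direction turned: the interferon list passed upward (median 1.39, 4 genes higher and none lower in limma, limma camera adjusted p = 6.09e-06), as did class I (median 0.94, limma camera adjusted p = 0.0287), and class II did not pass (median 0.49, limma camera adjusted p = 0.226). With an estimated correlation the adjusted p there was 0.618 for interferon and 0.724 for class I, and as above that covariate takes up much of the group difference.

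Mast cell, neutrophil, red cell and endothelial markers rose. The erythroid, neutrophil, endothelial and pericyte list means all climbed from PRC2 loss tumor 1 to tumor 3, so these rises may not be separate. The erythroid mean was 7.96, 9.45 and 11.86 and the neutrophil mean 6.79, 7.99 and 8.82 in tumors 1 to 3. The mast cell mean did not climb steadily, at 11.29, 11.16 and 12.47. Of 11 mast cell markers 10 rose and none fell (11 higher adjusted over the list alone; median 3.76): the mast cell chymase and protease genes Cma1 and Mcpt4 were 17.7-fold and 17.1-fold, the IgE receptor gene Fcer1a 18.9-fold and the histamine-making enzyme gene Hdc 10.1-fold higher. Of 18 endothelial markers 14 rose and none fell (15 higher adjusted over the list alone; median 1.66), with Vwf 6.72-fold, Sox17 5.75-fold, Emcn 5.33-fold and the cadherin gene Cdh5 4.32-fold higher. Of 14 neutrophil markers 10 rose and 2 fell, also adjusted over the list alone (median 3.53). The granule protein genes Ngp and Camp were 104-fold and 83.5-fold and S100a8 12.3-fold higher, and the cytokine gene Il1b was 22.9-fold lower; the other fall was Mmp9. Of 9 erythroid markers 6 rose and none fell (7 higher adjusted over the list alone; median 4.40), with the band 3 gene Slc4a1 144-fold higher and Hbb-bs 25.3-fold; globin genes have close copies, and Hbb-bs ranged from 11.02 to 16.71 among PRC2 loss tumors. Of 14 pericyte and smooth muscle markers 4 rose and none fell, also adjusted over the list alone (median 0.98), namely Rgs5 at 9.79-fold, Lmod1 at 9.72-fold, Myh11 at 8.59-fold and Notch3 at 3.83-fold higher. Limma's camera adjusted p was 2.31e-05 for mast cells, 4.5e-08 for endothelium, 0.00636 for neutrophils, 0.000683 for erythroid cells and 0.0109 for pericytes; with an estimated correlation the adjusted p was 0.456, 0.456, 0.518, 0.518 and 0.661. Centring on housekeeping genes ended the calls for neutrophils (limma camera adjusted p = 0.0595) and pericytes (0.0583), a replicate block also ended the pericyte call (0.0655), and averaging by animal number left 2 of the erythroid markers higher.

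**Figure D2:**
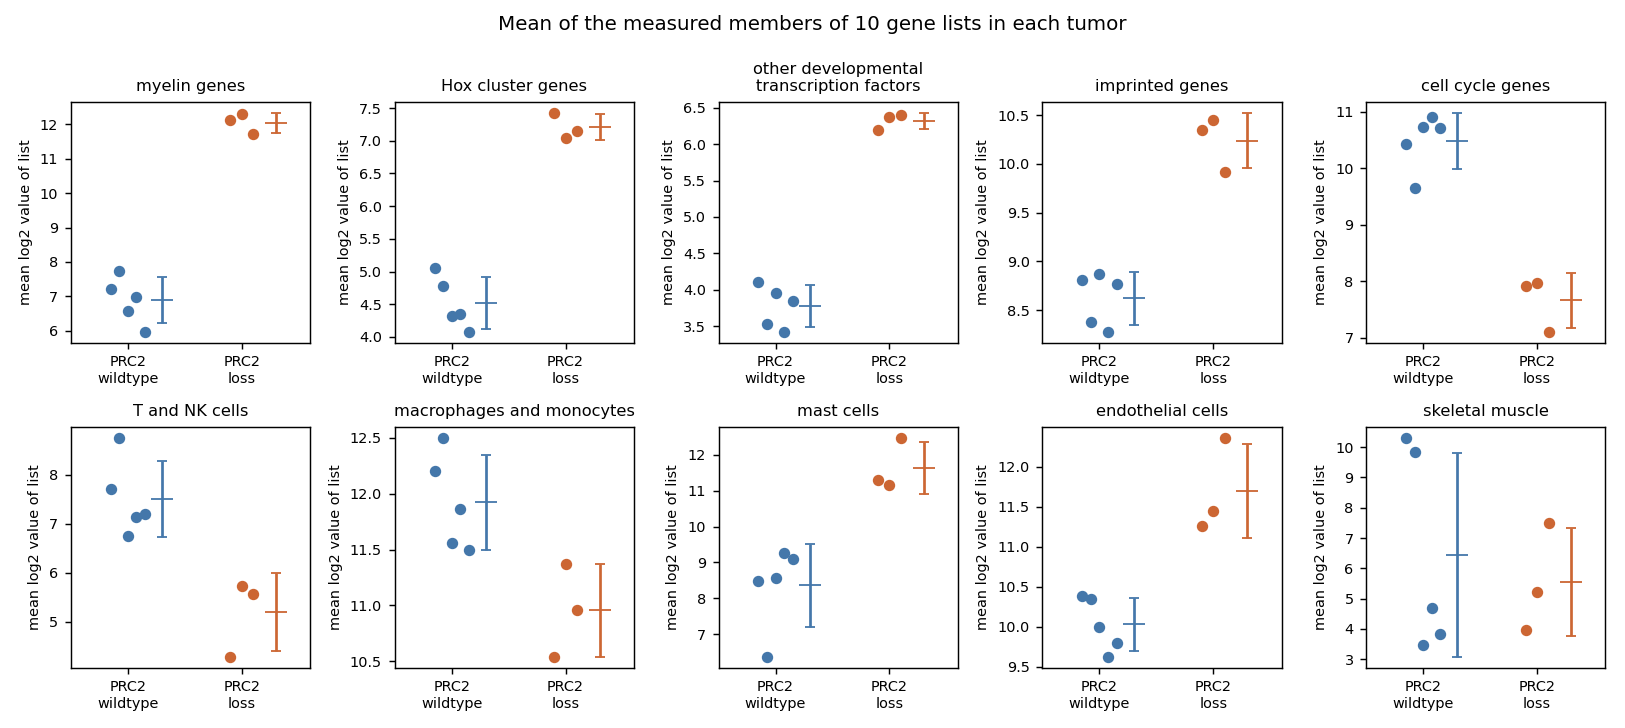
Mean log2 value of the measured members of 10 gene lists, with 1 point per tumor for the 5 PRC2 wildtype (blue) and 3 PRC2 loss tumors (orange) and the mean and SD beside them. The vertical axes differ between panels and do not start at 0; the groups separate in every panel but skeletal muscle, where the list mean averages 6.44 ± 3.36 in wildtype and 5.55 ± 1.79 in PRC2 loss.

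Among other tissue programs, 7 of 18 cartilage genes rose and none fell (8 higher and 1 lower adjusted over the list alone; median 1.57), including Cnmd, chondromodulin, at 162-fold and Col11a2 at 13.3-fold higher. Of 20 Wnt pathway target genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; median 1.07): the feedback inhibitor genes Nkd1 and Axin2 were 22.3-fold and 4.22-fold higher and the secreted modulator gene Dkk2 was 15.1-fold lower. Limma's camera adjusted p was 0.0151 for cartilage and 0.0237 for Wnt targets, adjusted p was 0.456 and 0.34 with an estimated correlation, and both calls were lost with housekeeping centring (limma camera adjusted p = 0.111 and 0.103) and with genes below the median mean left out (0.299 and 0.78); the macrophage covariate also ended the Wnt call (0.076). Of 28 skeletal muscle genes none changed in either direction in limma's test over all genes or adjusted over the list alone, and their list means lay at 10.31 and 9.85 in wildtype tumors 1 and 2 against 3.48 to 4.70 in the other wildtype tumors. Without those 2 tumors, a setting chosen after seeing the data, 4 of 28 muscle genes rose and none fell in limma's test (median 1.43, limma camera adjusted p = 0.00472, but adjusted p = 0.687 with an estimated correlation) and 7854 genes changed in all. Of 14 adipocyte genes none changed in limma's test, also adjusted over the list alone. Of 15 fibroblast genes 5 rose and none fell, also adjusted over the list alone (median 0.73): the matrix proteoglycan genes Lum and Dcn were 11.9-fold and 4.86-fold higher, Smoc2 9.38-fold and Fbln1 3.00-fold, with Cygb the fifth member. Averaging by animal number left 1 of these.

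The remaining lists changed in both directions. Of 28 collagen and matrix genes 2 rose (Dcn and Lum) and 5 fell, with Fn1, fibronectin, 5.78-fold, Timp1 4.86-fold and Thbs2 3.94-fold lower and Postn and Tnc, named after their values were seen, lower too. Of 26 glycolysis and hypoxia genes 4 rose and 10 fell (4 and 11 adjusted over the list alone), with the glycolytic enzyme genes Pgam1 and Tpi1 3.33-fold and 2.41-fold lower and Ndrg1, which is also a myelin gene, 10.7-fold higher; Slc2a1, Aldoc and Pdk1, named after their values were seen, rose. Of 23 immediate early genes 3 rose and 7 fell, with Fosb 11.3-fold, Junb 3.63-fold and Socs3 2.97-fold lower, Egr2 higher as above, and Egr3 and Nr4a1, named after their values were seen, higher. Of 21 germline genes 7 rose and 4 fell (9 and 4 adjusted over the list alone): Piwil4 was 15.5-fold higher and Ddx4 6.81-fold lower, with Dazl, Slc25a31 and Hormad1, named after their values were seen, lower. Of 12 bone genes 1 rose, the osteoblast factor gene Sp7 at 50.8-fold, and 1 fell, the mineral matrix gene Dmp1 at 73.9-fold. Of 14 epithelial genes 3 rose (Krt1, at 0 in all wildtype tumors, and Cdh1 and Dsp) and 3 fell (Epcam, Krt8 and Krt18, at 13.0-fold, 25.2-fold and 95.1-fold lower). Of 17 neuronal genes 2 rose, Rbfox3 and Prph, and 4 fell, with Nefl 58.1-fold, Nefm 30.5-fold and Stmn2 28.8-fold lower and Syn1 as the fourth (2 and 3 adjusted over the list alone). Collagen, immediate early, bone and epithelial counts were the same when adjusted over the list alone. None of these lists, nor fibroblasts, adipocytes and muscle, passed limma's camera in the planned fit to all 8 tumors (adjusted p from 0.0822 for germline genes to 0.939 for bone and adipocytes). Some passed upward in alternatives: germline genes with the lowest 25% of gene means left out (limma camera adjusted p = 0.00906) and without PRC2 loss tumor 3 (0.0392), epithelium without wildtype tumor 1 (0.0379), fibroblasts with the skeletal muscle covariate (0.0369), the macrophage covariate (0.00912) and without wildtype tumors 1 and 2 (0.00472), and muscle with the macrophage covariate (3.51e-05). With an estimated correlation in those same fits, in that order, the adjusted p was 0.195 and 0.438 for germline genes, 0.404 for epithelium, 0.508, 0.618 and 0.553 for fibroblasts and 0.618 for muscle. The bone list had a median of -0.13 while camera ranked it upward. The glycolysis, collagen and bone medians turned from negative to positive with housekeeping centring (0.10, 0.26 and 0.21). Gpi1 belongs to both the glycolysis list and the housekeeping set.

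**Figure D3:**
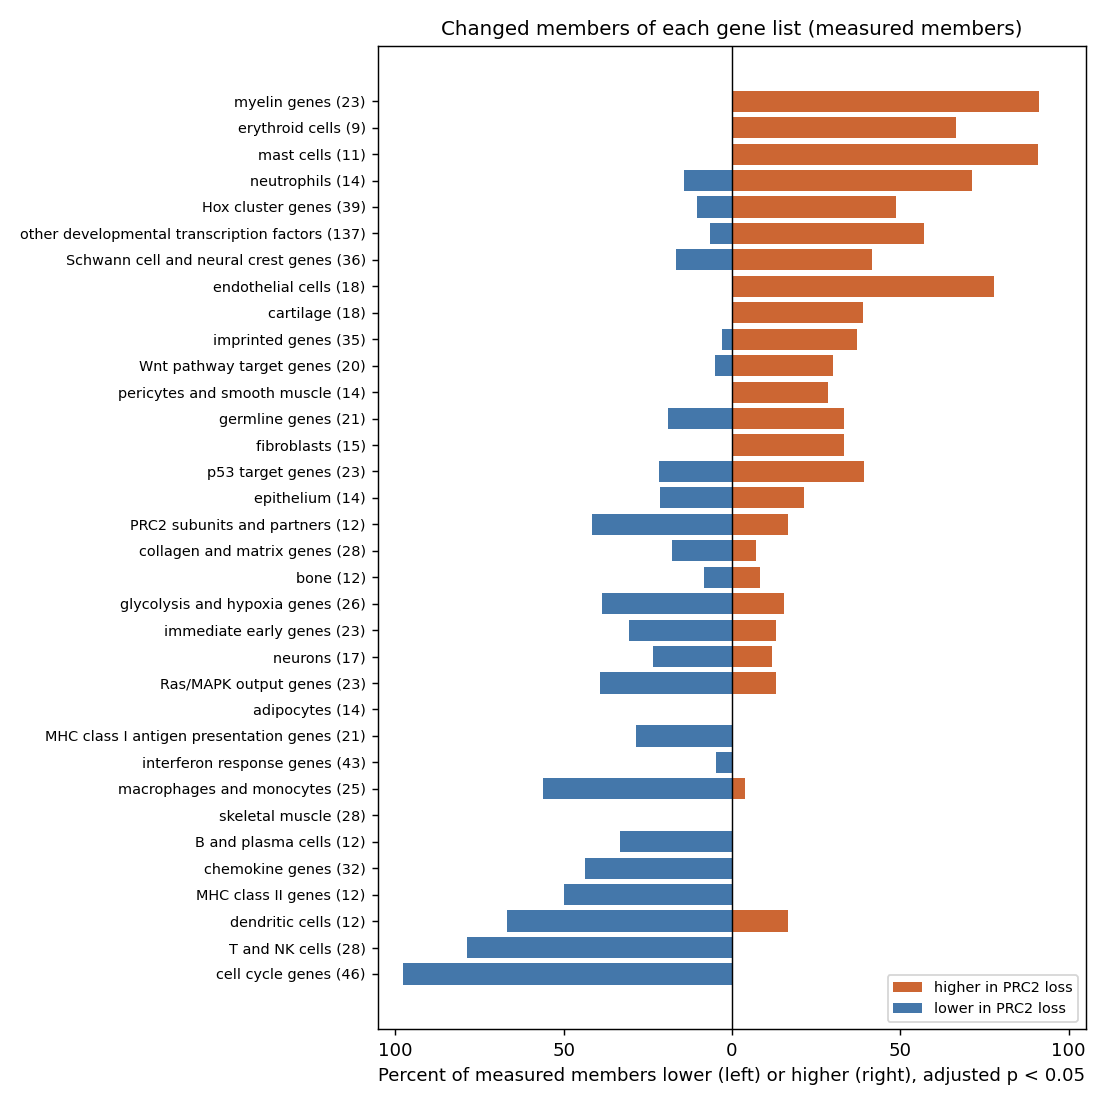
Percent of the measured members of each of 34 gene lists that were lower (blue, left) or higher (orange, right) in PRC2 loss at an adjusted p under 0.05, with lists ordered by median log2 difference and the number of measured members in parentheses. Myelin genes are at the top with 21 of 23 higher and cell cycle genes at the bottom with 45 of 46 lower; the glycolysis, collagen, bone and PRC2 medians turn positive with housekeeping centring.

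Across the 34 lists, 19 passed limma's camera with a preset correlation of 0.01, 12 higher and 7 lower in PRC2 loss, and 2 passed with an estimated correlation, the Hox and the other developmental transcription factor lists. Neither of these 2 passed that test in most alternatives, as given above. Fry, which asks whether the genes of a list move on balance in 1 direction, called 20 lists, and its mixed test, which counts changes in either direction, called 31. Male and female mice were present in both groups: wildtype tumor 5 and PRC2 loss tumor 1 held Y-linked transcripts such as Ddx3y at 12.11 and 12.09 and the lowest Xist, at 6.45 and 7.79, against 15.16 or more in the others. In the 6 other tumors, a setting chosen after seeing the data, 4623 genes changed. The PRC2 loss tumors left in that setting, 2 and 3, share 1 animal number.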

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

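The tests of tumor cell share and of normal nerve below were chosen after the results were seen. Those of chance, of matched lists and of the Eed region were set beforehand, the last without naming its filter on gene means.

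Among the 5 wildtype tumors, 21 of 200 genes or list means tested had 1 tumor far from the other 4 by Dixon's criterion, where chance alone gives about 1 in 20. Cnpy1, A2m, Hoxa13, Hoxb13 and Hoxc13 meet the criterion by construction, because 4 tumors were at 0 and 1 was above it, so that rate does not apply to them. Wildtype tumor 2 stood apart for 11 of them: Ccr7 at 10.97, H2-Oa at 9.439 and the B and plasma cell list mean at 8.802 lay above the other 4 tumors, Cma1 at 6.633, Mcpt4 at 6.961, the mast cell list mean at 6.372, Gtse1 at 8.348 and Rbbp7 at 12.69 lay below, and Cnpy1 at 1.849 and both Hoxa13 and Hoxc13 at 1.176 were above 0 where the other 4 were at 0. Wildtype tumor 5 stood apart for the sex-linked genes Ddx3y at 12.11, Eif2s3y at 11.09, Kdm5d at 10.64 and Xist at 6.453, and for Hoxb13 at 1.704. Wildtype tumor 1 had A2m at 1.13 and an epithelium list mean of 6.85, against 3.829 or less in the others. Wildtype tumor 3 had Gzmb at 5.628 and Mtf2 at 10.95, and wildtype tumor 4 had Jarid2 at 9.733.

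The real grouping of the tumors gave 7424 changed genes. It was the only 1 of the 56 splits into 5 and 3 tumors to give as many, and the highest other split gave 803, with wildtype tumors 3, 4 and 5 against the rest. If the 8 tumors are independent, this makes chance assignment to groups unlikely. It does not exclude it, since 1 of 56 is the smallest share this design allows. Tumors sharing an animal number had deviation correlations of 0.511 (wildtype 1 and 2), 0.198 (wildtype 3 and 4) and -0.258 (PRC2 loss 2 and 3). These were the highest within their groups, though wildtype 3 and 5, with different animal numbers, had 0.174. The consensus correlation with animal number as a block was 0.345, so independence is doubtful. The labels leave open whether tumors sharing an animal number come from 1 mouse; keeping such tumors together leaves 6 splits, too few for a share under 0.05, and the highest other of these also gave 803. The labels name a nerve of origin for PRC2 loss tumors alone, so tumor site is not separated from PRC2 status.

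Hox genes and other developmental transcription factors were higher in PRC2 loss, where fewer genes were listed at 0. A general lift of low genes would give a median like that of other low genes, but both list medians lay at the percentile of 100 among 10000 random lists matched on mean value, whose middle 95% ran from -0.70 to 0.41 for Hox genes. The matched lists argue against that explanation. Release of genes that PRC2 represses remains a candidate explanation, found and examined in the same tumors, and tumor site, which also sets Hox expression in nerve-associated cells, is not separated from it.

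Myelin genes were higher and cell cycle genes lower in PRC2 loss. If a lower share of tumor cells lifted markers of every other cell type alike, mast cell and T and NK cell markers would change together. The mast cell mean rose by 3.28 while the T and NK cell mean changed by -2.31, a difference of 5.59 (SE 0.984). That argues only against such a uniform lift. It cannot count against a lower tumor cell share in which the other tissue has its own mix of cells. Normal nerve left on the PRC2 loss tumors cannot be told apart from a change in the tumor cells. The lowest myelin mean at a named nerve site exceeded the highest of the other tumors by 3.98 on the log2 scale, and no wildtype tumor has a named nerve site (0 of 5). Eed does not decide either, since Plp-CreERT may recombine normal Schwann cells too; the remaining 0.389-fold Eed level can come from any cell.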

How the results depend on the processing

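Fits without the male tumors and without the PNC8 tumors (wildtype 1 and 2) were chosen after seeing the data. Eed stayed lower and past the limma threshold in all 26 alternatives (adjusted p from 7.65e-05 to 0.0382), and every gene called both there and with all 8 tumors kept its direction. Leaving out 1 tumor at a time gave 5528 to 7697 changed genes, 2555 to 3413 higher and 2972 to 4284 lower, 17 to 23 lists and an Eed difference of -1.40 to -1.30. With genes below the median gene mean left out, 4248 genes changed (1715 higher, 2533 lower) and 10 lists passed; fewer genes and members were tested. Housekeeping centring gave 5332 higher and 2267 lower genes, by a common shift of each tumor. Averaging by animal number gave 4226 (2113 each way), with fewer samples; the animal number as a block gave 5926. Female tumors alone gave 4623 (2204 higher, 2419 lower), with fewer samples. There the PRC2 loss group was tumors 2 and 3, which share 1 animal number, as in the fit without PRC2 loss tumor 1. Neither fit separates PRC2 status from that animal number. An estimated correlation left 2 lists, Hox genes and other developmental factors, which then passed in 6 and 9 of 25 alternatives. Neither did with animal numbers averaged (limma camera adjusted p = 0.238 and 0.0513 with an estimated correlation) or housekeeping centring (0.274 each). The replicate block (0.401 each) and sex as a covariate (0.0706 each) also ended both calls. The replicate block gave 1903 genes (1129 higher, 774 lower); same-numbered tumors had deviation correlations of -0.208, 0.146 and -0.095, so the numbers do not pair tumors. Among lists with a call in either fit, the Hox median turned with genes below the median left out (-0.42). That filter removes the Hox genes near 0 in wildtype. The skeletal muscle median turned without the PNC8 tumors (1.43). Under the macrophage covariate, medians turned for interferon (1.39), MHC class I (0.94), MHC class II (0.49), skeletal muscle (4.16) and, by construction, macrophages (0.03). Beyond that filter and that construction, the cause was not tested. Among lists without a call in either fit, medians also turned for B and plasma cells (0.60), adipocytes, p53 targets, collagen and bone under that covariate, for PRC2 subunits, collagen, glycolysis and bone with housekeeping centring, and for fibroblasts, p53 targets, collagen, bone or adipocytes in 8 other settings. In all settings together, the 165 named genes lost a call 193 times and gained one 13 times, and lists 57 and 42 times; none of the genes reported here turned with a call, and 61 sign changes came with no call in either fit. Single tumors left out ended calls for Suz12, Aebp2, Ifi44l, Pdia3, H2-Oa, H2-Ob, Ppia, Jchain, Dcn, Lum, Fbln1, Lmod1, Myh11 and Rbfox3 (limma adjusted p up to 0.123) and gave calls for Cdkn2a and Phf1. Depth is unknown, so no counting error can be given for low values.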

Other observations

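The Eed region test below was set before its result was seen, though the prediction did not name its filter on gene means. The families and genes of the next 2 paragraphs were chosen after seeing the data.

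Some families that were not fixed lists themselves held several changed genes, and no enrichment test was run on them. The globins overlap the erythroid list above, which holds Hbb-bs and Hba-a2 among others, so their rise is not a separate observation. The neuronal list holds the synaptotagmin gene Syt1. Of 20 semaphorin genes, axon guidance ligands, 10 rose and 2 fell in PRC2 loss; Sema3a fell by 5.72 on the log2 scale (13.06 ± 1.04 in wildtype, n = 5, and 7.34 ± 0.42 in PRC2 loss, n = 3). Of 17 synaptotagmins, calcium sensors of vesicle release, 8 rose and none fell in limma's test, and 4 of 8 globin genes rose. Of 20 Ly49 receptor genes (Klra), 14 fell, with a median log2 difference of -3.55; these are near-identical copies that can share reads and vary between mouse strains. Apod, a lipid carrier of nerve fibroblasts and Schwann cells, rose from 13.36 ± 1.38 to 18.66 ± 0.18, and Fmo2 from 9.54 ± 1.03 to 15.90 ± 0.35. In PRC2 loss tumors 2 and 3 Apod stood at 18.764, the highest value of every tumor after normalization. Its PRC2 loss mean and SD are therefore limited by that ceiling. Hmga1, a relative of Hmga2, fell by 3.86, and Cdkn2b, the neighbour of Cdkn2a that encodes p15, fell by 2.01 (limma adjusted p = 0.0129).

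In further gene families the lower counts depended on scaling, except for CCT chaperonin subunits, where 7 of 9 fell in both scalings. Over all genes tested 19.6% fell. Of 78 mitochondrial ribosomal protein genes 50 fell and 1 rose, of 40 proteasome subunits 24 fell, of 9 CCT chaperonin subunits 7 fell, of 13 LSM proteins 11 fell and of 77 cytosolic ribosomal proteins 15 fell, which is 19.5% and no more than over all genes. Centred on housekeeping genes, the lower counts were 20, 6, 7, 6 and 5. Over all 20807 genes, 2267 fell with that centring against 4087 without it. The 19.6% is therefore not the background for the centred counts. With that centring 2 mitochondrial ribosomal, 1 proteasome and 5 cytosolic ribosomal genes were higher. Of the 15 housekeeping genes 7 themselves fell and none rose in limma's test (median -0.377). They include the proteasome subunit genes Psmb2 and Psmb4, so the proteasome count after centring is not independent of the scaling. The family medians stayed negative in both scalings, at -0.297 for mitochondrial ribosomal, -0.288 for proteasome and -0.035 for cytosolic ribosomal genes after centring.

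Large differences were frequent near Eed on chromosome 7, where a strain variant carried along with the Eed allele is a candidate explanation. Among genes with a mean at or above the median, 18 of 161 within 20 Mb of Eed differed at least 4-fold (11.2%, Wilson 95% interval 7.19 to 17%), 8 higher and 10 lower, against 5.89% elsewhere on the autosomes. That share lay at the percentile of 96.95 among 6547 windows of as many neighbouring genes, just under the bound set beforehand. The interval of the share covers percentiles from 70.2 to 100, so the test leaves the explanation open. Trim12a fell from 9.93 ± 0.64 to 1.17 ± 0.67 and Trim30d from 10.66 ± 0.33 to 5.99 ± 1.52, and Gm1966 fell by 6.65 on the log2 scale, all on the distal side of Eed and all in families of close copies whose reads can be shared. Trim34b nearby rose from 3.03 ± 0.76 to 7.30 ± 0.74, and Trim12c did not pass the test (limma adjusted p = 0.377). Trim12a, Gm1966 and Trim34b have means below the median and are not among the 18. Trim5, 28.9-fold lower, is left out in the same way. The filter takes the mean over all 8 tumors, so genes near 0 in either group tend to be left out. The share does not count them, which limits the test.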
